A study of Mus musculus with 5 samples.

How the data were processed

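Genomic DNA from spleen myeloid cells was measured by array comparative genomic hybridisation, in which 2 labelled DNA samples compete for the same probes and the ratio of their signals reports relative copy number. The 5 arrays were Agilent CGH microarrays, and each held DNA of 1 βcat(ex3)osb mouse and 1 wild-type mouse, per the labels. The array titles name the wild type as C57BL/J. The mutant DNA carried Cy5 and the wild-type DNA Cy3 on all 5 arrays, so no array had swapped dyes. Mice were 5 weeks old and labelled female, and 2 µg of DNA went into a labelling reaction, per the labels' protocols. The labels give 1 mouse of each genotype per array. They do not say whether a mouse was used on a second array, so p-values measure the spread between these 5 arrays.

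The deposited values were log2 ratios, 1 per probe and array, for 13269 probes with no missing value. The submitters' processing notes name Agilent Feature Extraction 10.7.3.1 and genome build mm9. Whether values were centred, how they were normalized, and how these 13269 probes were chosen are not given in the sources used here. The log base was inferred from the values. A highest value of 7.60 cannot be a log10 ratio on a 20-bit scanner scale, which ends at 6.02, whereas natural logs cannot be excluded. The array titles put the mutant before the wild type and Agilent ratios are by convention Cy5 over Cy3, so a higher log ratio likely means more mutant DNA. This direction is not stated in the sources used here, and text on higher and lower ratios refers to the deposited sign. Scanner intensities were not used here, so signal over background is unknown and the number of arrays limits the precision.

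Probes were identified by name only. None of the first 200 probe names occurred in the gene table used here, and no other source used here paired probes with genes or positions. The planned tests of genes, of fixed gene lists (among them leukaemia genes, the Wnt and Notch pathways, and the B and T cell receptor loci as a measure of lymphocyte DNA) and of whole chromosomes were therefore not run. The planned rule named at most 2 probes that rose and 2 that fell, by mean log ratio among probes past the threshold with the same sign on all 5 arrays.

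Choices made before the data were examined were as follows. Each array was centred on its median over all probes, without loess or quantile steps. limma 3.58.1 in R 4.3.3 (lmFit with an intercept, then eBayes) tested each probe's mean over the 5 arrays against 0, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Probes beyond 0.58 either way, the log2 ratio of 3 copies over 2, were counted per array. Alternatives were values without centring, scaling of each array to the mean median absolute deviation (MAD), a robust eBayes, array weights, a test against 0.1, another log base, filters on probes, and leaving out each array in turn.

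The following steps were chosen after seeing the data. Probe names start with A_53 (1597 probes) or A_67 (11672 probes). A_67 probes were sorted by the number in the name and split into runs wherever consecutive numbers differed by more than 2000, which gave 77 runs. The 4 runs with at least 500 probes were called long runs and the other 73 short runs. The last 606 probes of the last long run, from the first probe of a block with array 1 log ratios over 1, were kept apart as the final stretch. Number order is not a genome position. The planned search for gained and lost segments was run in this order, with each class of probes centred on its own median and the final stretch left out. A running median of 5 probes had to exceed 0.3 and a level that 20 shuffles of the same array passed at most 1 time per shuffle. Segments of the same sign that overlapped on at least 2 arrays were called recurrent stretches. Medians of the recurrent stretches over arrays were not tested, because the stretches were chosen by their ratios on the same arrays. The difference between the final stretch and the long runs was tested on arrays 2 to 5 by exact two-sided sign flips, whose smallest possible p with 4 arrays is 0.125. Python 3.11.15 with numpy 2.4.6 and scipy 1.17.1 was used for these steps.

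Both procedures were tested on simulated data. With 13269 probes on 5 arrays at the observed spread, the limma fit recovered 26 of 50 probes changed by 0.25, 39 of 50 changed by 0.5, 45 of 50 changed by 1 and 48 of 50 changed by 2, with 6 false calls among 164. Noise was drawn independently for each probe and array. It held no shift of a probe class on array 1 and no dye effect shared by the arrays. False calls from these sources in the real data were therefore not measured. The segment search recovered 20 of 20 stretches of 15 probes shifted by 1 on every simulated array, with 0 false stretches beside them and at most 1 where none had been added. These stretches were placed in the long runs only, with probes of all classes shuffled together. Recovery of shorter or smaller shifts, and false stretches particular to the short runs, were therefore not measured. The threshold came from further shuffles of the same values, so a low number of false stretches was set in advance. Shuffling also removed any likeness between neighbouring probes, so false stretches in the real order were not measured.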

Results

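Myeloid cells were taken from the spleens of βcat(ex3)osb mice, which carry an activated form of β-catenin in osteoblasts and are studied as a model of leukaemia arising from changes in the bone, and their DNA was compared with wild-type DNA on 5 arrays. The comparison asks whether myeloid cells of the mutants had gained or lost DNA. The reference on each array was DNA of another mouse, named C57BL/J in the array titles. Inherited differences between the mice of a pair, of strain among others, therefore cannot be told apart from changes in the myeloid cells. Each array held 1 mutant and 1 wild-type mouse, and the table gave 13269 probes on each. Genes and chromosomes were not assigned to the probes, because no source used here paired them. Results are therefore given by probe and by groups of probes.

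Over all probes of this table, the median lay close to a ratio of 1 on arrays 2 to 5 but not on array 1. The median deposited log2 ratio was -0.83 on array 1, a ratio of 0.561. It was -0.04 on array 2, -0.08 on array 3, -0.09 on array 4 and -0.02 on array 5. The spread over probes was also largest on array 1, with an SD of 0.951 against 0.271, 0.259, 0.338 and 0.235 on arrays 2 to 5. Its MAD of 0.242 lay within the range of 0.159 to 0.298 of the other arrays, so the larger SD came from a tail of high ratios reaching 7.60. No pair of arrays shared identical values at any probe. Across probes, which are not independent replicates, all 10 pairs of arrays correlated positively, with Spearman's rho from 0.609 to 0.888 and Pearson's r from 0.416 to 0.873.

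**Figure D1:**
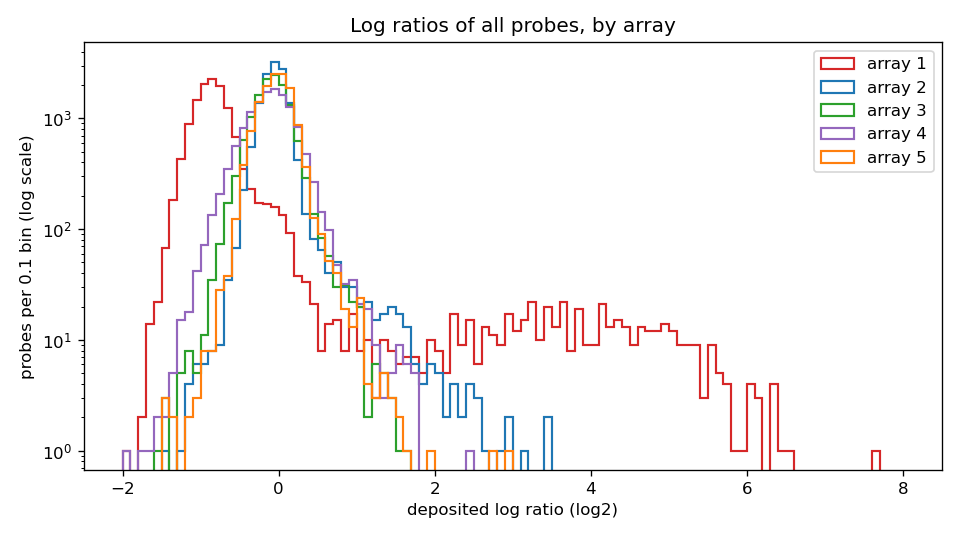
Number of probes (log scale) per 0.1 of deposited log2 ratio for each of the 5 arrays. Arrays 2 to 5 peak near 0, whereas array 1 peaks near its median of -0.83 and has a tail that reaches 7.60.

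The low and the high ratios of array 1 belonged to separate groups of probes. In the 10390 probes of the long runs, the array 1 median was -0.86 (ratio 0.550), and in the 1597 A_53 probes it was -0.84 (ratio 0.557). In the 676 probes of the short runs it was -0.08, close to the medians of -0.05, -0.13, -0.17 and -0.05 on arrays 2 to 5. With these groups, the long runs lay below the short runs by a log2 difference of -0.78 on array 1, and the difference was -0.13 when runs were split at gaps of 500 in place of 2000. That split puts 2010 long-run probes, with an array 1 median of -0.82, into the short class beside the 676 probes at -0.08. On arrays 2 to 5 the long runs had medians of -0.05, -0.09, -0.10 and -0.03.

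The final stretch of 606 probes was higher than the other probes on every array, and by far the most on array 1. Its median was 3.37 on array 1, a ratio of 10.3, and 538 of the 606 probes exceeded a log2 ratio of 1. Only 3 of the other probes did so on that array. The medians on arrays 2 to 5 were 0.60, 0.34, 0.41 and 0.30. The final stretch exceeded the long runs on 5 of 5 arrays, by 1.23 ± 1.68 (SD, n = 5). Array 1 ratios set the start of the stretch, so the difference was tested on the other 4 arrays, where it was 0.48 ± 0.13 (SD, n = 4; exact two-sided sign-flip p = 0.125, the smallest that 4 arrays allow).

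**Figure D2:**
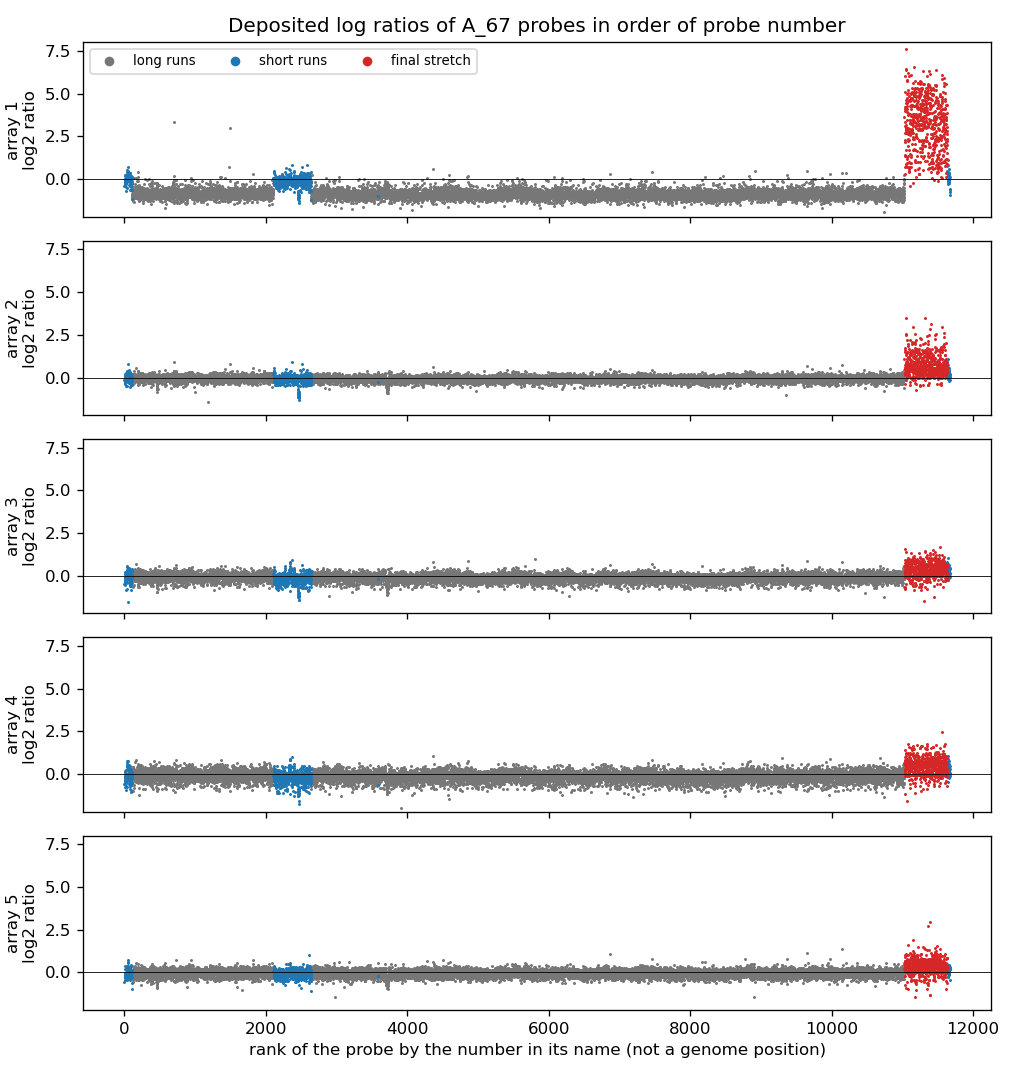
Deposited log2 ratio of each of the 11672 A_67 probes on the 5 arrays, ordered by the number in the probe name, with long runs in grey, short runs in blue and the final stretch in red. On array 1 the long runs lie near -0.86 and the final stretch has a median of 3.37, whereas the short runs lie near 0 as on the other arrays.

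Runs of neighbouring probes that stood above or below the median of their probe class were found on every array. The search called 7 segments on array 1, 5 each on arrays 2, 3 and 4, and 3 on array 5. Of the 6 higher segments on array 1, 5 had deposited medians below 0, so they were less shifted than the long runs around them and not above a ratio of 1. Of these, 7 recurrent stretches overlapped on at least 2 arrays, 3 with lower and 4 with higher ratios. The stretches were chosen by their ratios on these arrays, so their medians over arrays were not tested against 0.

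A stretch of 19 probes was lower on arrays 1 to 4 and was not called on array 5. Its median log2 ratio was -1.01 ± 0.17 (SD over probes) on array 1, -1.02 ± 0.20 on array 2, -1.08 ± 0.22 on array 3 and -0.99 ± 0.31 on array 4, which are ratios of 0.496, 0.494, 0.473 and 0.503. With the values read as log2, a difference of 1 copy against 2 would give 0.5. On array 5 the median was -0.17 ± 0.22. Windows of 10 probes gave the same 4 arrays, and windows of 3 probes covered at least 0.5 of the stretch on arrays 2 and 3 alone. The 40 flanking probes had medians of -0.10, -0.05, -0.19, -0.21 and -0.01 on arrays 1 to 5. Both probes with the lowest mean log ratios over all arrays, A_67_P08232246 and A_67_P08232501, lay in this stretch.

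A stretch of 27 probes within the long runs had nearly equal ratios on all 5 arrays. Its median was -0.59 on array 1, -0.60 on array 2, -0.61 on array 3, -0.64 on array 4 and -0.54 on array 5, a mean of -0.60 ± 0.04 (SD, n = 5). It was called over most of its length on arrays 2, 3 and 5 and over 9 probes on array 4, while the flanking probes of arrays 2 to 5 had medians of -0.03, -0.08, -0.02 and -0.09. On array 1 the flanking probes were themselves at -0.72, so the stretch stood 0.12 above them and was not called. Windows of 10 probes called at least 0.5 of the 27-probe stretch on arrays 2 to 5, and windows of 3 probes on array 2 alone. A 15-probe stretch in another long run showed the same arrangement, with a mean of -0.46 ± 0.07 (SD, n = 5). It was called on arrays 2 and 5, and on array 1 it lay 0.31 above its flanking probes. Windows of 10 probes called it on arrays 2 to 5, and windows of 3 probes on 0 arrays. On array 1, a segment of 5 probes called higher overlapped the start of the 15-probe stretch, with a deposited median of -0.35.

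**Figure D3:**
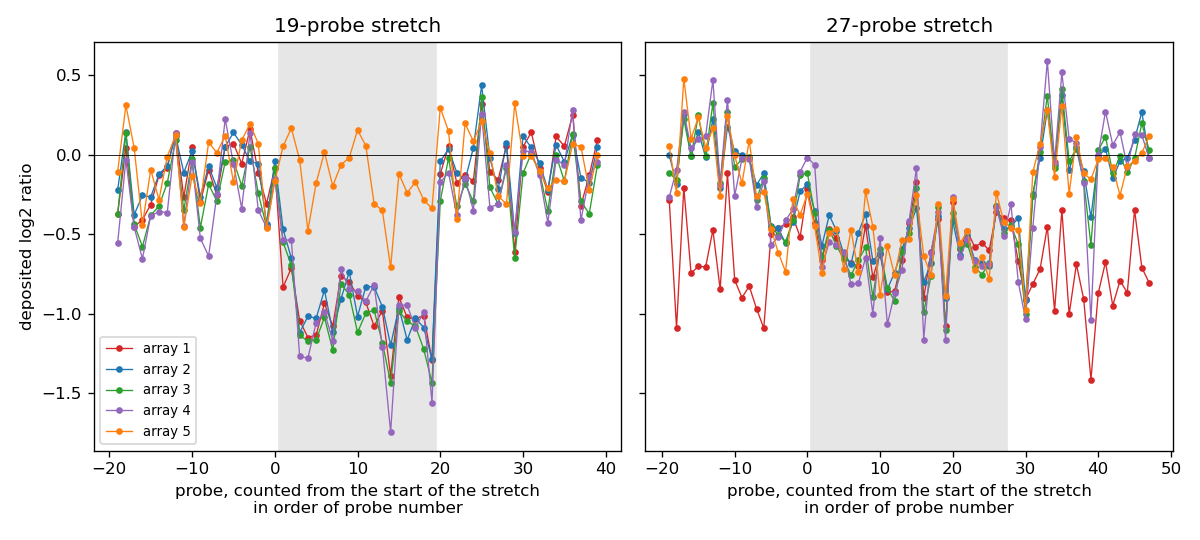
Deposited log2 ratio of each probe in the 19-probe stretch (left, grey band) and the 27-probe stretch (right, grey band), with 20 flanking probes on each side in order of probe number, 1 line per array. In the 19-probe stretch arrays 1 to 4 lie near -1 and array 5 at a median of -0.17, and in the 27-probe stretch all 5 arrays lie together while array 1 is lower in the flanking probes.

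The recurrent stretches with higher ratios were short. A stretch of 6 probes had medians of 0.61 on array 3 and 0.65 on array 4, ratios of 1.52 and 1.57, against 0.11, 0.13 and 0.09 on arrays 1, 2 and 5. Windows of 3 probes called it on the same arrays, and windows of 10 probes on 0 arrays. A difference of 3 copies against 2 would give 0.58 on the log2 scale. A stretch of 8 probes was called on arrays 1 to 4, with medians of 0.46, 0.39, 0.42 and 0.43, and had a median of 0.19 on array 5. Its flanking probes, which took in the 9-probe stretch described next, were themselves at 0.17, 0.13, 0.26, 0.21 and 0.19 on arrays 1 to 5. Against them, the 8-probe stretch stood 0.29, 0.26, 0.16 and 0.22 higher on arrays 1 to 4, and on array 5 it was level. Windows of 10 probes called it on the same 4 arrays, and windows of 3 probes on arrays 2 and 3. A 9-probe stretch close by in probe number was called on arrays 3 and 4 at 0.38 and 0.31, and lay between 0.26 and 0.29 on arrays 1, 2 and 5. It stood 0.12, 0.20, 0.24, 0.19 and 0.16 above its flanking probes on arrays 1 to 5. Those took in the 8-probe stretch, so each of these stretches was compared partly with the other. Windows of 10 probes called the 9-probe stretch on all 5 arrays, and windows of 3 probes on 0 arrays. The remaining stretch, 6 probes at the edge of the final stretch, was called on arrays 1 and 5 relative to the other long-run probes, with deposited medians of -0.15 and 0.31. Windows of 10 probes called it on array 1 alone, and windows of 3 probes on 0 arrays.

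Probe by probe, the total number of shifts called depended on the centring while array 1 was in the fit. After centring each array on its median, limma called 6208 of 13269 probes at an adjusted p of 0.05, of which 2829 were higher and 3379 lower. It called 740 without centring and 103 when arrays were centred on the short runs, which do not carry the array 1 shift, an alternative added after seeing the data. The median absolute log2 ratio of the 6208 called probes was 0.22, with quartiles of 0.16 and 0.31. Of the called probes, 114 had a mean over 0.58 (3 copies over 2) and 1 a mean under -1 (1 copy over 2). These bounds differ in size, so the counts do not compare gains with losses. All 5 arrays had the same sign at 7665 probes (57.8%), where independent signs would give 6.25%. Because the dyes were never swapped, differences between the dyes and between the genotypes enter this test alike.

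The 4 probes named by the planned rule were in the final stretch and in the 19-probe stretch. A_67_P09497793 had a mean centred log2 ratio of 2.91 ± 2.28 (SD, n = 5; limma adjusted p = 0.0371), and A_67_P09496725 had 2.85 ± 2.10 (SD, n = 5; limma adjusted p = 0.0311). On array 1 they stood at 6.70 and 6.44. Both calls held without array 1, where their means were lower, at 1.96 and 1.96 (limma adjusted p = 0.0064 and 0.0040). Neither call held with the robust eBayes (limma adjusted p = 0.0653 and 0.0563), against a bound of 0.1 (0.0707 and 0.0606), or without array 2 (0.094 and 0.0829), array 3 (0.0639 and 0.0529) or array 4 (0.0887 and 0.0605), and that of A_67_P09496725 was also lost without array 5 (0.0584). A_67_P08232246 had a mean of -1.08 ± 0.46 (SD, n = 5; limma adjusted p = 0.00676), and A_67_P08232501 had -0.97 ± 0.54 (SD, n = 5; limma adjusted p = 0.0135), a call lost without array 3 (limma adjusted p = 0.0513).

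The number of called probes depended on how array 1 was treated. Without centring, limma called 740 probes, 219 higher and 521 lower, of which 549 were also called after centring. Without centring and without array 1, it called 6317 probes, 1986 higher and 4331 lower. With centring and without array 1 it called 6324, 3039 higher and 3285 lower, so the balance of directions still moved. With centring, leaving out array 3 reduced the count to 3514. Centring on this table sets the long runs of array 1 to 0 and raises its short runs. After centring, 71 of the 676 short-run probes were called higher and 15 lower, against 5 higher and 34 lower without centring.

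Probes beyond 0.58 either way after centring numbered 1435 on array 1, 411 on array 2, 439 on array 3, 1023 on array 4 and 279 on array 5. On array 1 most of these, 1343, were higher, and on array 4, which had the largest MAD, 457 were higher and 566 lower. Without centring, 10714 probes of array 1 lay below -0.58, whereas arrays 2 to 5 had 77, 347, 911 and 103 such probes. Above 0.58 without centring lay 596 probes of array 1, and 325, 191, 309 and 176 of arrays 2 to 5.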

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

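Apart from the planned limma test, the tests in this part were chosen after the results were seen. Of 20 sets of 5 array values, 7 had an array farther from the others than Dixon's 95% critical value of 0.71 allows. Chance gives about 1 in 20 for unselected and independent sets, which these are not. The medians of all probes, of the A_53 probes and of the long runs share 1 shift, the final stretch was defined by array 1, and the stretches were chosen by the arrays they were called on. For array 1 these were the median of all probes at -0.83 (next array -0.09), the SD over probes at 0.951 (next 0.338), the median of the A_53 probes at -0.84 (next -0.13), the median of the long runs at -0.86 (next -0.10) and the median of the final stretch at 3.37 (next 0.60). For array 5 they were the median of the 19-probe stretch at -0.17 (next -0.99) and the median of the 8-probe stretch at 0.19 (next 0.39).

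On array 1, most probes lay near the ratio of 1 copy over 2 and the final stretch near 10.3. An offset of the whole array is argued against by the short runs, which lay at -0.08 on the same array (long runs minus short runs -0.78, or -0.13 with gaps of 500, which add 2010 probes at -0.82 to these 676). A noisier hybridisation is argued against by the MAD of the long runs, which was 0.723 times that of array 4, the highest, although above those of arrays 2, 3 and 5, while the long-run median of array 4 was -0.10. A candidate explanation is that the 2 mice on array 1 were of different sex, contrary to their labels: the long runs and A_53 probes would then lie on X (median -0.86 in the long runs, expected -1) and the final stretch on Y, which is missing from 1 of the DNAs. This stays open because the probes were not placed on chromosomes here, and a loss of one chromosome in these cells would not by itself give ratios of 10.3 elsewhere. A difference of sex on array 1 also leaves the final stretch on arrays 2 to 5 unexplained. Its medians there were 0.60, 0.34, 0.41 and 0.30, with long-run medians of -0.05, -0.09, -0.10 and -0.03.

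The 19-probe stretch was near -1 on arrays 1 to 4 and at -0.17 on array 5. A dye effect of these probes would recur on arrays of the same orientation, and a full-copy difference carried by every mutant would recur in each pair. Both stay open, because only array 5 departs from them (median -0.17, difference from flanking probes -0.16) and 1 array gives no measure of the spread between hybridisations. A difference of 1 copy against 2 within a mouse pair may account for 4 arrays, which had medians within 0.2 of -1. Whether it was inherited, arose in the myeloid cells or lies in the wild-type mice as a gain was not tested, and a genotype effect present in fewer cells of pair 5 stays open.

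The limma calls were 6208 with the arrays as labelled, and 0 in each of the other 15 of the 16 sign patterns. In those, all log ratios of some arrays change sign, which reverses dye and genotype together. Any effect that a probe shows alike on all arrays favours the real pattern, so these counts cannot tell genotype from dye. At an unadjusted p of 0.05 limma gave 7459 probes for the real pattern and at most 1563 for another. In all, 1 pattern, the real one, gave as many. With 16 patterns a share under 0.05 cannot be reached. A gain or loss of a whole copy relative to the array median in every mutant is argued against for most calls. Of the called probes, 89.8% had a 95% interval inside 0.58 either way. The intervals are of centred values, so a shift shared by most probes of an array cannot show in them. A dye effect of each probe stays open, since 0 arrays had swapped dyes. A change in a minority of cells also stays open and was not tested.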

How the results depend on the processing

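The limma count moved with centring while array 1 was in the fit, and with other choices. The 6208 limma calls (2829 higher, 3379 lower) became 740 (219 and 521) without centring, 103 (72 and 31) when arrays were centred on the short runs, an alternative added after seeing the data, and 2406 (922 and 1484) against a bound of 0.1. Leaving out each array in turn gave 3514 to 6324 calls, 1436 to 3039 higher and 2078 to 3285 lower, with the lowest counts without array 3. Without array 1, the count was 6324 (3039 higher, 3285 lower) with centring and 6317 (1986 and 4331) without it. Array weights gave 7876 calls, and the other alternatives stayed within 1.5 times. A change of log base or a minimum of 3 arrays cannot move this count, since they rescale all values or remove no probe. Probes beyond 0.58 on arrays 1 to 5 (1435, 411, 439, 1023 and 279) became 3429, 1359, 2550, 4258 and 2026 at a bound of 0.3, and 725, 183, 72, 154 and 54 at a bound of 1. Read as natural logs (added after seeing the data) they were 2239, 742, 1305, 2519 and 875, and without centring array 1 had 11310. With windows of 3 probes the segments numbered 2 on array 1 and 9 on array 5, and with windows of 10 probes 5 on array 5. The array 1 shift of the long runs against the short runs, -0.78, was -0.13 when runs were split at gaps of 500, which moves long-run probes into the short class. With the mean over probes, the 15-probe stretch moved from -0.46 to -0.53, and the 6-probe stretch beside the final stretch reversed from 0.021 to -0.0203. The latter ranged from -0.0507 (without array 5) to 0.0631 when each array was left out. Calls of A_67_P09497793 and A_67_P09496725 were lost under 5 and 6 alternatives (limma adjusted p from 0.0064 to 0.094 and 0.004 to 0.0829), A_67_P08232501 only without array 3 (0.0513), and A_67_P08232246 under none that tested it. No named probe was tested once the tenth of probes with the highest SD was left out. No tests of genes, gene lists or chromosomes were run, because probes were not named. The cause of these changes was not tested where none is given. Without intensities, what signal over background limits is unknown.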

Other observations

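The test in this part was chosen after the result was seen. The short runs held a mixture of small shifts. Of the 50 short runs with at least 3 probes, 29 had a median deposited log ratio below 0 on all 5 arrays, 9 above 0 on all 5, and 12 of mixed sign. The median of all short-run probes was itself below 0 on every array. Relative to that median, 13 runs lay above it on all 5 arrays, 15 below it on all 5, and 22 on both sides. The deposited mean over arrays ranged from -0.29 to 0.31 between runs. How these probes came to be in the table is not given in the sources used here, so a choice made on these values by the submitters would also produce agreement between arrays.

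A hypothesis used throughout is that A_67 numbers follow genome order, which may be why neighbouring numbers shared their values. The rank correlation between neighbours over all 11672 A_67 probes was 0.329, 0.166, 0.161, 0.141 and 0.0787 on arrays 1 to 5, each with a permutation p of 1.0e-05, the smallest that 100000 permutations give (1.7e-05 after Benjamini-Hochberg adjustment over 15 tests). Within the longest run of 6102 probes it was 0.0683, 0.0601, 0.1, 0.0757 and 0.025, and the last of these did not pass (permutation p = 0.0531, adjusted 0.0797). The 1597 A_53 probes ordered by number gave values between -0.0387 and 0.0093, none of which passed. Any other order in which the probes were designed could give similar values.

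The 27-probe and 15-probe stretches kept their deposited ratio on array 1, at -0.59 and -0.50, although the long-run probes around them were shifted there and not on arrays 2 to 5. No explanation was tested.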
